A study of Mus musculus with 2 samples.

How the data were processed

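The assay was ChIP-seq, in which chromatin is immunoprecipitated and its DNA sequenced, with an antibody against H3K9me3, histone H3 trimethylated at lysine 9, a mark of silenced chromatin. The tissue was whole heart of mouse embryos at embryonic day 12.5, strain B6NCrl, pooled male and female per the labels. The labels number 2 biological replicates, which were separate biosamples under the same donor identifier. They form 1 group, so no comparison between conditions was possible.

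Per the submission's file lists, the authors made 4 peak lists on build mm10. Each replicate had a list of its own, a further list was called on both replicates together, and the replicated list was made from these. Each deposited peak carries a fold enrichment, which is a ratio, together with a −log10 p-value, a −log10 q-value and the distance of its summit from its start, all from the authors' peak caller. The peak caller and its version, its threshold, what the fold was taken over, and the rule for the replicated list are not given in the sources used here. The labels name a control experiment, which was not used here. The files hold no read counts, so the sequencing depth is unknown and no counting interval is given. The fold of a peak is the authors' and serves here only to describe and rank peaks. Folds in the replicates come from lists called separately, and their mean ± SD is over those 2 values. Each is the fold of the replicate's peak that overlaps the replicated peak most, which need not be the strongest peak of that replicate in the gene.

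Coordinates are 1-based on mm10, which is GRCm38. The reference was the GRCm38 genome with the GENCODE mouse annotation, and 55413 genes with 132721 transcript starts lay on the 21 assembled chromosomes. Peaks on other sequences were left out of the main results. A peak of a replicate counted as shared when at least 50% of its length was covered by peaks of the other. A gene body counted as marked when a replicated peak lay in it with at least 50% of its length. A promoter counted as marked when a replicated peak touched the 1 kb on either side of any annotated transcript start of the gene. Members of 23 gene lists were taken by symbol or name pattern, and 1 symbol, Dux, had no match in the annotation. The pattern for histone genes also takes histone variants.

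Tests compared the peaks with their own positions after a circular shift. All peaks of a chromosome were moved together by a random distance along its non-gap sequence, with 1000 shifts, or 100 for sequence composition. The two-sided permutation p was 2 times the smaller tail, so the smallest p these can give is 0.0020, or 0.0198 with 100 shifts. These p-values come from placement along the genome, not from the spread between replicates. Benjamini-Hochberg adjustment ran over the 23 lists, separately for bodies and promoters, and over the 5 annotation classes, with a threshold of 0.05. As a description, each list's marked share of bodies was set against 10000 random lists of the same size matched on gene length in 20 bins. Those values are not given below. The calls below thus compare a list with shifted peak positions, not with other genes. Coverage of zinc finger genes was taken over Zfp-named genes with at least 3 exons and a body of at least 5 kb. Annotation classes took the midpoint of a peak in the order promoter, coding exon, UTR or non-coding exon, intron, intergenic. The promoter class there was 1 kb on either side of any annotated transcript start of any gene. The exon classes likewise took exons of any annotated transcript of any gene. Replicated peaks within 5 kb were merged into domains. The planned shift test of domains was void, since a shift keeps the spacing of peaks, so random placement of single peaks, planned elsewhere as an alternative, took its place.

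Genes were named by a rule. It takes the 10 protein-coding genes of at least 2 kb with the largest share of the body covered and the genes at or nearest to the 10 replicated peaks of highest fold. It also takes up to 4 genes in each of the 5 longest domains, and of each list up to 4 marked members with the highest fold at a peak found in both replicates. Cardiomyocyte and cardiac transcription factor genes with a marked promoter and 12 imprinting control genes complete it. Other genes named in the text were chosen after their values were seen. The lists, the rule, the tests and most alternatives were fixed before the data were examined. The full peak lists of each replicate alone, the counts of recurring 31-mers, the distance to the nearest peak and the scan of gene families were added after seeing the data.

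The tests of gene lists, zinc finger exons, annotation, composition, overlap, families, domains and promoters by GC content were run on simulated data. Unless adjusted calls are named, all counts from these runs use unadjusted p-values. Each run used 200 placements, but 500 for families and 50 for composition. With the replicated peaks shifted, so that no list differed from chance, the gene list test gave p-values below the threshold in 1.96% of 460 tests of bodies. For promoters the share was 2.39% of 460 tests, over all 55413 genes, with 0 adjusted calls for either. With 200 placements a list alone at the smallest p cannot pass adjustment, so the absence of adjusted calls says little. Peaks were then added to 5%, 10% and 20% of a list of 200 genes. By unadjusted p, bodies were found above chance in 3, 12 and 20 of 20 runs. Promoters were found so in 7, 20 and 20 of 20. Small excesses in gene bodies would thus often be missed. Recovery by the adjusted p, which decides the results, was not measured. The zinc finger exon test over 349 genes gave p-values below the threshold in 0 of 20 unchanged runs and recovered added coverage of 5%, 10% and 20% in 20 of 20. The annotation test gave 2.0% of 50 unchanged tests and recovered 10 of 10 added excesses. The composition test gave 0 of 10 unchanged tests, and no difference was added for it. The overlap test first gave p-values below the threshold in 3 of 20 unchanged runs, or 15%. The number was raised to 100 with other random draws after that was seen, which gave 6.0%. It recovered added shares of 1% and 5% in 20 of 20. The family scan gave p-values below the threshold in 4.86% of 2550 unchanged tests over 8146 genes. By unadjusted p it found 99 of 100 families with coverage added to 10% of each member's body. Recovery by the adjusted p of the reported scan, with its 5000 shifts, was not measured. The domain test, simulated with peaks placed singly, gave 0 of 20 unchanged runs and found 5 and 10 added domains in 20 of 20 runs each. The test of promoters by GC content gave 5.0% of 100 unchanged tests. With peaks added at 1% of the promoters in the highest GC bin, which marked 4.35 points more of these overlapping windows, it found the excess in 20 of 20 runs. No deficit was simulated for any test.

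The alternatives were stricter q-value thresholds of −log10 q of at least 2 and 5, other overlap rules, either replicate left out, pooled peaks, random placement, other windows and merging distances, and other gene sets. With 1 replicate left out, the other's list was cut to its 68224 peaks of highest −log10 p, as many as the replicated peaks used. The pooled list was cut in the same way. Results without replicate 1 and from the full list of replicate 2 thus both rest on replicate 2 peaks, and the reverse holds for replicate 1. Computation used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, numba 0.67.0 and matplotlib 3.10.9.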

Results

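H3K9me3 was mapped in the heart of mouse embryos at embryonic day 12.5, in 2 biological replicates of mixed sex. Replicate 1 had 110809 peaks and replicate 2 had 123270. The list called on both replicates together held 180355 peaks. The replicated list held 68508, each identical in position to a pooled peak. On the 21 assembled chromosomes, 68224 replicated peaks covered 30.7 Mb, or 1.16% of the non-gap sequence. Their median width was 376 bp and their median fold 3.43. Median widths in the replicates were 231 and 226 bp, with median folds of 3.22 and 3.24. A replicated peak lay in the body of 9254 of 55413 annotated genes, or 16.7%, and touched the promoter of 3949, or 7.13%. The read depth behind these lists is unknown.

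The first question was how far the replicates marked the same positions. Of replicate 1 peaks, 35.1% (38784 of 110460) were covered for at least 50% of their length by replicate 2 peaks, against 1.33% after circular shifts. Of replicate 2 peaks, 31.9% (39241 of 122931) were covered by replicate 1 peaks, against 1.25%. With 1 bp of overlap these shares were 43.9% and 39.8%, with at least 50% of both peaks 28.1% and 25.3%, and with at least 80% of the peak's length 20.3% and 18.8%. For the main rule both permutation p-values were 0.0020, the smallest the shifts can give. With lists of equal length the main shares were 33.2% and 33.3%. They are both directions of 1 comparison, so no spread between replicates can be given for them. Across 37412 pairs of shared peaks, folds were only weakly related, with a Spearman correlation of 0.217. That correlation is across peaks, which are not independent replicates. Of the replicated peaks, 49.5% (33739) were covered to that extent by peaks of both replicates and 5.55% by peaks of neither. With a −log10 q of at least 5 required in the replicates' lists alone, 3.39% of the 68224 replicated peaks were covered by both.

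Zinc finger genes of the C2H2 type, most of which encode DNA-binding repressors, carried the mark in many gene bodies. A replicated peak lay in 225 of 472 bodies of KRAB and other C2H2 genes, or 47.7%, against 33.6% after shifts. Among the Zfp-named genes within that list it lay in 207 of 399, or 51.9%, against 34.1%. Both lists had an adjusted permutation p of 0.0115. In the full lists of the replicates, 59.6% ± 1.8 (SD, n = 2) of Zfp-named bodies were marked. Those lists held 110460 and 122931 peaks, against 68224 replicated ones. Shares of genes marked in them, here and below, are thus not comparable with the shift values given for replicated peaks. Within these lists, which were taken by name and leave out Klf14, the highest folds at peaks found in both replicates were in Zfp110 (10.6; 5.53 ± 0.66 in the replicates, SD, n = 2) and Zfp930 (10.4; 7.77 ± 2.6). Zfp68 followed at 10.3 (8.51 ± 0.49) and Zfp777 at 10.1 (8.28 ± 2.3). By their midpoints, these peaks lay in an intron (Zfp110), within 1 kb of some annotated transcript start (Zfp930 and Zfp68) and in a coding exon (Zfp777, on chromosome 6 from 48023107 to 48026747). The Zfp930 peak, from 69225442 on chromosome 8, overlapped the pseudogene Gm33178, while the 5' end of Zfp930 is at 69209038. The Zfp68 peak, from 138605729 on chromosome 5, was also far from that gene's 5' end at 138619761. The highest fold of any peak in the Zfp110 body was 11.6 in replicate 1 and 6.69 in replicate 2. With random placement of single peaks, neither body list passed the test, with an adjusted permutation p of 0.648 for C2H2 genes and 0.0804 for Zfp-named genes. Promoters of the same genes were marked in 59 of 472 C2H2 genes, or 12.5% against 11.2% (adjusted permutation p = 0.694). For Zfp-named genes the promoter count was 53 of 399, or 13.3% against 11.3% (adjusted permutation p = 0.615).

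Counted by bases, coverage within these genes was highest over the last coding exon, where the zinc fingers are mostly encoded. In 349 Zfp-named genes, replicated peaks covered 22.9% of the bases of last coding exons, 1.59% of promoter bases and 2.41% of intron bases. Chance coverage was 1.69%, 1.56% and 1.41%. The exon exceeded the promoter by 21.3 percentage points, while the highest of 1000 shifts gave 2.23 (permutation p = 0.0020, the smallest possible). In the full lists of the replicates the difference was 19.1 points ± 1.5 (SD, n = 2). Counted by genes, 28.1% had a peak in the last coding exon, 4.87% at the promoter and 43.0% in introns, which are far longer, against 5.08%, 6.77% and 30.02% after shifts. Most of these genes thus had no peak in that exon.

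**Figure D1:**
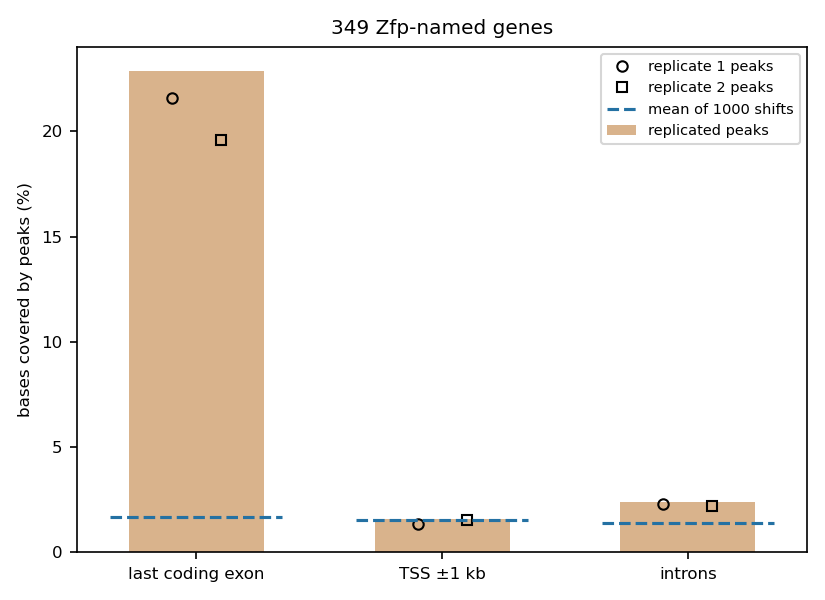
Share of bases covered by peaks (percent, vertical axis) in the last coding exon, promoter and introns of 349 Zfp-named genes, with bars for replicated peaks, symbols for each replicate's own list and dashed lines for the mean of 1000 shifts. Last coding exons reached 22.9% with replicated peaks, while promoters and introns stayed at 1.59% and 2.41%.

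Clustered protocadherin genes, which encode cell adhesion proteins used by neurons for cell recognition, were the list with the largest marked share. A replicated peak touched 53 of 57 promoters, or 93.0% against 5.42% after shifts, and 53 of 57 bodies, or 93.0% against 52.3% (adjusted permutation p = 0.0115 for each). Both replicates marked 52 promoters and 53 bodies in their full lists. The 4 unmarked promoters, Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5, all belong to the C-type genes at the ends of the clusters, of which Pcdhac1 was marked, and were singled out after their values were seen. The strongest shared peak was at Pcdhb22, on chromosome 18 from 37521622 to 37522101, with a fold of 8.64 (7.55 ± 0.50 in the replicates, SD, n = 2). Pcdha1, Pcdha2 and Pcdha3, whose annotated bodies overlap, shared a peak from 36999620 to 37000369 with a fold of 7.90 (6.11 ± 2.2). Its midpoint lay in a coding exon of some annotated gene, not necessarily of these. It was far from their 5' ends at 36930184, 36939205 and 36946105. The longest domain of merged peaks lay in the gamma cluster, on chromosome 18 from 37656259 to 37777713. It spanned 121455 bp and held 69 peaks that covered 52.2% of it.

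**Figure D2:**
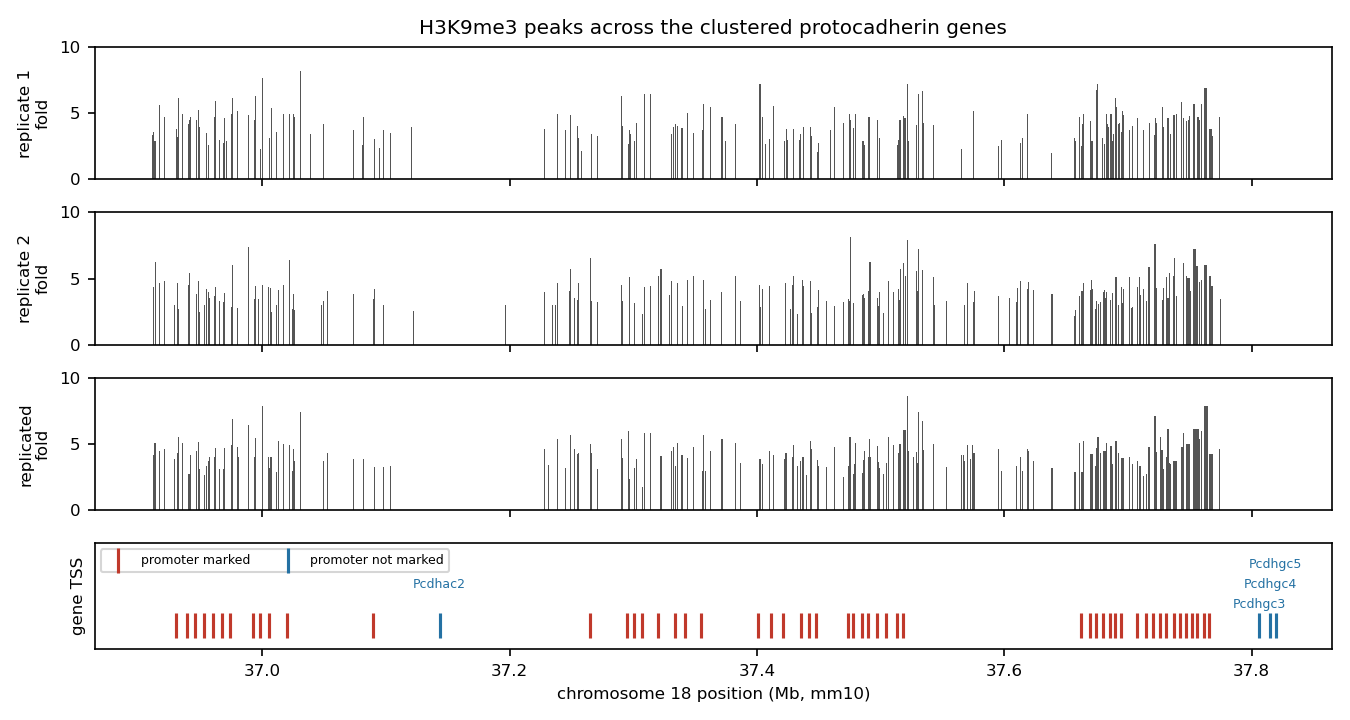
Map of the protocadherin clusters on chromosome 18 (position in Mb, horizontal axis), with the peaks of each replicate and the replicated peaks as bars of their fold, and below them the starts of the 57 genes, red where the promoter was marked and blue where not. The 4 blue starts are those of Pcdhac2, Pcdhgc3, Pcdhgc4 and Pcdhgc5.

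Imprinted genes, which are expressed from a single parental allele, were marked at 28 of 41 promoters, or 68.3% against 15.1% after shifts. Their bodies were marked in 32 of 41, or 78.0% against 41.1% (adjusted permutation p = 0.0115 for each). In the full lists of the replicates, 68.3% of promoters were marked in each. Klf14, a Krüppel-like transcription factor gene expressed from the maternal allele, had a peak on chromosome 6 from 30956253 to 30959059 with a fold of 11.5 (10.9 ± 0.50 in the replicates, SD, n = 2). Peaks covered 92.1% of its body. Mest, a paternally expressed gene, reached 8.42 (7.78 ± 0.83) at a peak with its midpoint within 1 kb of an annotated transcript start. Meg3, a maternally expressed non-coding RNA, reached 7.87 (7.27 ± 0.48), and Peg13, a paternally expressed non-coding RNA, 7.86 (6.59 ± 0.54). Among the imprinting control genes, folds were 7.13 at Peg3 (6.42 ± 0.82), which encodes a zinc finger protein, and 6.85 at Snrpn (5.52 ± 0.22), in the Prader-Willi region. They were 6.37 at Grb10 (5.43 ± 2.2), an adaptor of growth factor receptors, and 5.83 at Gnas (5.34 ± 0.76), a G-protein subunit. Nnat, encoding neuronatin, had 5.77 (6.12 ± 0.24) and Kcnq1ot1, a paternally expressed antisense RNA, 5.66 (6.04 ± 0.84). Impact had 5.57 (7.20 ± 1.7), Peg10 5.0 (5.14 ± 1.5) and Igf2r, a scavenger receptor for insulin-like growth factor, 3.38 (3.21 ± 0.14). The Plagl1 promoter peak, with a fold of 5.36, overlapped a peak of replicate 2 but none of replicate 1. H19, a maternally expressed non-coding RNA, had neither a marked body nor a marked promoter. Its nearest replicated peak lay 1683 bp away, with a fold of 4.03.

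**Figure D3:**
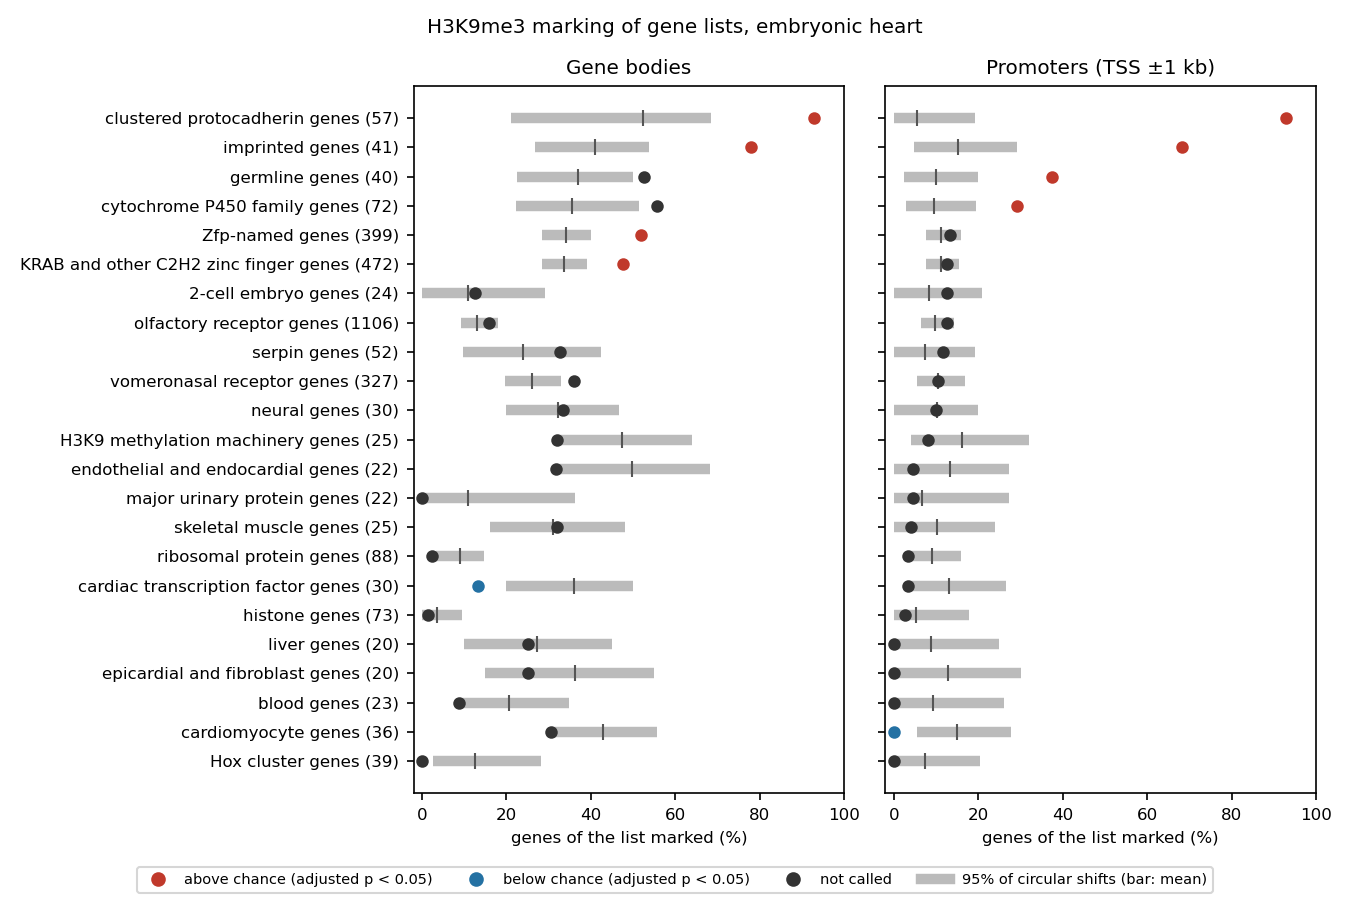
Share of genes marked (percent, horizontal axis) in the 23 gene lists, for bodies and for promoters, with points for replicated peaks, red above chance, blue below and black not called, grey bars for 95% of 1000 shifts and ticks for their mean. Protocadherin genes reached 93.0% in both panels and imprinted genes 68.3% at promoters, while cardiomyocyte promoters were at 0.

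Germline genes, which act in oocytes, spermatocytes and their precursors, were marked at 15 of 40 promoters, or 37.5% against 10.1% after shifts (adjusted permutation p = 0.0115). The replicates' full lists gave 41.2% ± 5.3 (SD, n = 2), but without replicate 2 the test was not passed (adjusted permutation p = 0.0919). Bodies were marked in 21 of 40, or 52.5% against 36.9% (adjusted permutation p = 0.115). Taf7l, a germ cell subunit of a general transcription factor, had a promoter peak with a fold of 7.0 (6.28 ± 0.018 in the replicates, SD, n = 2). Nlrp5, an oocyte protein needed for early cleavage, had 5.81 (5.13 ± 0.45) and Mov10l1, a helicase of the piRNA pathway, 5.63 (5.20 ± 1.4) within an intron. Tdrd9 had 4.76 (3.87 ± 1.2). Cytochrome P450 genes, many of them enzymes of the adult liver, were marked at 21 of 72 promoters, or 29.2% against 9.56% (adjusted permutation p = 0.0115). That call was lost with a −log10 q of at least 5 (adjusted permutation p = 0.175), without replicate 2 (0.171) and with pooled peaks (0.0551). Their bodies were marked in 40 of 72, or 55.6% against 35.6% (adjusted permutation p = 0.0574), and were called above chance with pooled peaks (0.0131), in the full list of replicate 2 (0.0322) and when extended by 5 kb (0.0077). Cyp3a11, Cyp3a44 and Cyp2c39 had folds of 6.42 (5.64 ± 0.29), 5.69 (5.24 ± 0.057) and 5.66 (5.09 ± 0.90).

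Other gene families did not pass the test in bodies or promoters with replicated peaks, though several did under alternatives. Olfactory receptor bodies were marked in 175 of 1106 genes, or 15.8% against 13.1% (adjusted permutation p = 0.402), and promoters in 138, or 12.5% against 9.76% (0.522). Vomeronasal receptor bodies were marked in 118 of 327, or 36.1% against 26% (adjusted permutation p = 0.0574), and promoters in 34, or 10.4% against 10.3% (1.0). Vomeronasal bodies were called above chance with a −log10 q of at least 5 (adjusted permutation p = 0.0184), without replicate 1 (0.0230), without replicate 2 (0.0460), with pooled peaks (0.0131), in the full list of replicate 2 (0.0322) and with bodies extended by 5 kb (0.0345). Olfactory receptor bodies were called above chance when extended by 5 kb (adjusted permutation p = 0.0077). Their promoters were called so in the full list of replicate 2 (0.0328), from 2 kb upstream to 0.5 kb downstream (0.0383) and within 5 kb (0.0115). The strongest peaks were in Olfr5 (5.37) and Vmn2r10 (7.0). Serpin genes, which encode protease inhibitors, were marked in 17 of 52 bodies and 6 promoters, with adjusted permutation p-values of 0.414 and 0.615. The strongest shared peak was in Serpina1b (5.66). No body of 39 Hox genes and none of their promoters was marked, against 12.6% and 7.29% after shifts (adjusted permutation p = 0.115 and 0.434). The full lists of replicates 1 and 2 marked 5 and 8 Hox bodies and 3 and 6 promoters. The strongest 68224 pooled peaks, the cut used for that alternative, marked no Hox body and no promoter. With random placement Hox bodies were called below chance (adjusted permutation p = 0.0115). Ribosomal protein genes were marked in 2 of 88 bodies and 3 promoters (adjusted permutation p = 0.0574 and 0.245). Their bodies were called below chance in the full list of each replicate (adjusted permutation p = 0.0092 for each), without replicate 2 (0.0092), among protein-coding members (0.0230), with random placement (0.0077) and when extended by 5 kb (0.0077). Their promoters were called so in each full list (0.0230 for each) and within 5 kb of transcript starts (0.0115). Histone genes were marked in 1 of 73 bodies, that of H2afy2, which encodes a macroH2A variant, and 2 promoters (0.711 and 0.912). Major urinary protein genes were marked in 0 of 22 bodies and 1 promoter (adjusted permutation p = 0.334 and 1.0). Genes of the 2-cell embryo were marked in 3 of 24 bodies and 3 promoters (1.0 and 0.789), the bodies being Usp17lb, Usp17la and Duxf3.

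Of 30 cardiac transcription factor genes, which direct the formation of the heart, 4 had a marked body, or 13.3% against 36.1% after shifts (adjusted permutation p = 0.0184), and the full list of each replicate gave the same call, with 16.7% ± 4.7 marked (SD, n = 2). That call was lost when the body was extended by 5 kb (adjusted permutation p = 0.0689), and no body was covered to 10%. Genome-wide, 29.0% of peak midpoints were intronic, against 39.7% after shifts. A deficit of marked bodies against shifts thus need not be particular to these or other listed genes. Mef2a had an intron peak with a fold of 4.89 (4.20 ± 0.99). Of their promoters 1 was marked, that of Nr2f1, an orphan nuclear receptor (adjusted permutation p = 0.402 for the list). The 1 peak in the Nr2f1 body, with a fold of 2.64 and its midpoint in a coding exon, overlapped a peak of replicate 2 but none of replicate 1. The full lists of replicates 1 and 2 marked 1 and 0 promoters of cardiac transcription factor genes. These promoters were called below chance in the full list of replicate 2 (adjusted permutation p = 0.0092) and within 5 kb of transcript starts (0.0115). Cardiomyocyte genes, which encode contractile proteins and ion channels, had 0 of 36 promoters marked, against 14.9% (adjusted permutation p = 0.0368). In the full lists of the replicates, 1 and 5 of these promoters were marked. The call was lost in the full list of replicate 2 (adjusted permutation p = 0.607), without replicate 1 (0.230), without replicate 2 (0.0919), with pooled peaks (0.0551), with a −log10 q of at least 5 (0.236) and within 5 kb of transcript starts (0.0843). Bodies of cardiomyocyte genes were marked in 11 of 36, or 30.6% against 42.9% (adjusted permutation p = 0.195), and were called below chance in the full list of replicate 1 (0.0131) and with random placement (0.0077). Those with the strongest shared peaks were Scn5a, the cardiac sodium channel (6.44; 5.93 ± 1.5), and Cacna1c, a calcium channel (5.49; 5.16 ± 0.33). Gja5, a gap junction protein (4.75), and Sgcg, a sarcoglycan (4.47), followed, and all 4 peaks lay in introns.

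Markers of other cells in or near the heart passed the test in neither bodies nor promoters with replicated peaks. Endothelial and endocardial genes were marked in 7 of 22 bodies, among them the growth factor receptor genes Flt1 and Tek, and 1 promoter (adjusted permutation p = 0.167 and 0.615). Epicardial and fibroblast genes, among them Pdgfrb, were marked in 5 of 20 bodies and 0 promoters (0.485 and 0.402). Blood genes were marked in 2 of 23 bodies, among them the macrophage receptor gene Adgre1, and 0 promoters (0.253 and 0.501). Neural genes were marked in 10 of 30 bodies and 3 promoters (1.0 and 1.0). Among them, Slc17a7, a vesicular glutamate transporter, had a peak with a fold of 8.50 (7.68 ± 1.4 in the replicates, SD, n = 2). The midpoint of that peak lay within 1 kb of an annotated transcript start, and peaks covered 43.1% of the gene body. Syt1, a calcium sensor of synaptic vesicles, had an intron peak of 8.04 (6.74 ± 0.62). Liver genes were marked in 5 of 20 bodies, among them Hnf4a, and 0 promoters (adjusted permutation p = 1.0 and 0.594). Skeletal muscle genes were marked in 8 of 25 bodies, among them Pax7, and 1 promoter, that of the calcium release channel gene Ryr1 (1.0 and 0.694). Genes of the H3K9 methylation machinery were marked in 8 of 25 bodies, among them the methyltransferase gene Setdb1 and the demethylase gene Kdm4a, and 2 promoters (adjusted permutation p = 0.247 and 0.615). Under alternatives, bodies were called below chance for endothelial genes in the full list of replicate 2 (adjusted permutation p = 0.0131) and with random placement (0.0115). The same held for blood genes in that full list (0.0172) and for the methylation machinery with random placement (0.0077).

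Across the genome, peaks lay mostly between genes. Their midpoints were intergenic in 62.1%, against 50.5% after shifts, and intronic in 29.0%, against 39.7% (adjusted permutation p = 0.0033 for each). UTRs and non-coding exons held 2.01% against 2.39% (adjusted permutation p = 0.0033), promoters 5.81% against 6.41% (0.0075), and coding exons 1.09% against 1.02% (0.196). In the full lists of the replicates, 60.95% ± 0.021 (SD, n = 2) were intergenic. The promoter deficit became a small excess when bases were counted (6.61%, adjusted permutation p = 0.515). Peaks had a GC content of 48.7% against 42.0%, and 38.7% of their bases were soft-masked repeats against 34.1% (permutation p = 0.0198 for each, the smallest 100 shifts can give).

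Chromosome 7, which holds many zinc finger and vomeronasal genes, had the most peaks per Mb, at 77.5 ± 2.96 (SD, n = 2) in the replicates' lists, followed by chromosome 17 (66.4 ± 2.18) and chromosome 5 (59.4 ± 2.15). Chromosome 14 had 34.1 ± 3.85 and X 30.8 ± 2.30. Y had 0.93 ± 0.50 and, like X, has another copy number in tissue of mixed sex. Copy number was not tested as the cause of either value, and neither was sequence that recurs within the chromosome. Among replicated peaks, the density of chromosome 7 was 1.98 times that of the genome and that of X 0.66 times.

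**Figure D4:**
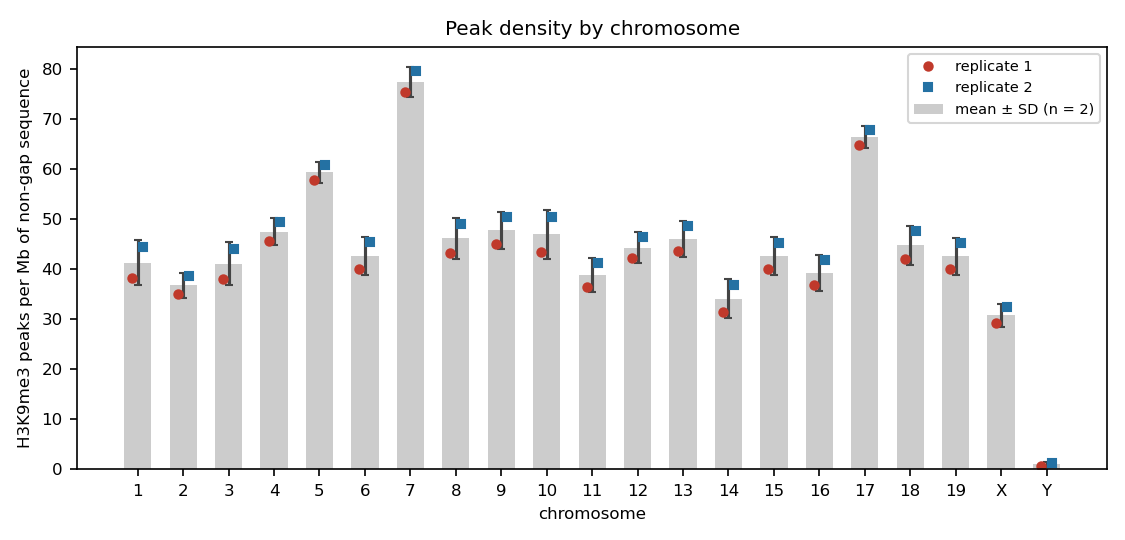
Peaks per Mb of non-gap sequence (vertical axis) on each of the 21 assembled chromosomes (horizontal axis), as bars for the mean of the 2 replicates, error bars for the SD and points for each replicate. Chromosome 7 stands highest at 77.5 and Y lowest at 0.93.

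Merging replicated peaks within 5 kb gave 42048 domains, of which 275 were at least 20 kb long, against a mean of 0.748 and a maximum of 6 after random placement (permutation p = 0.0020, the smallest possible). Random placement scatters peaks called side by side in 1 broad region. The p-value thus shows that peaks cluster, and any mark called as adjacent peaks would exceed this placement. After the gamma protocadherin domain, the longest spanned 113688 bp on chromosome 7 from 17936799 to 18050486, over Ceacam11 and Ceacam13, members of a family of cell adhesion genes. Another on chromosome 7, of 107408 bp from 47683641 to 47791048, held the pseudogene Mrgprc3-ps. A domain of 100490 bp on chromosome 4 from 121565235 to 121665724 covered Gm12887, and 1 of 86884 bp on chromosome 7 from 33557202 to 33644085 covered the secretoglobin pseudogenes Scgb2b22-ps and Scgb1b22-ps. With merging within 2 kb there were 22 such domains, against 0 after random placement. Within 10 kb there were 1029, against a mean of 329 and a maximum of 381, so the ratio to chance was far smaller there.

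The replicated peak of highest fold, 13.1, lay at the promoter of Tcfl5, a basic helix-loop-helix gene expressed in testis, on chromosome 2 from 180642510 to 180643944. The next, 12.4, lay on Y from 259045 to 259451, at 51256 bp from its nearest gene Gm29277. It was followed by an intron peak of C230088H06Rik and Gm26624 on chromosome 4 (11.7) and by that of Klf14. A peak near Gm5165 on chromosome 17 and that of Zfp110 had 10.6 each, and Asmt, which encodes the last enzyme of melatonin synthesis, had 10.1 (7.74 ± 1.3 in the replicates, SD, n = 2). Among the genes most covered over their bodies were the secretoglobin genes Scgb2b3 (96.6% of the body) and Scgb2b24 (95.9%), Asmt (95.7%), Klf14 (92.1%), the oocyte homeobox gene Obox8 (89.3%) and G6pd2 (89.0%), a testis-expressed copy of glucose-6-phosphate dehydrogenase.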

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

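The only result outside the main measurement came from sequences not placed on the 21 assembled chromosomes. They held 284 replicated peaks on 28 sequences, with 349 peaks in replicate 1 and 339 in replicate 2. The unplaced sequence JH584304 held 64 of the replicated peaks, with 70 and 72 in the replicates. The median fold of these peaks was 3.42, against 3.43 on the assembled chromosomes, and the highest was 9.18. No gene list or region result above uses these peaks, and no explanation was tested for them.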

How the results depend on the processing

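The full lists of either replicate were tried only after seeing the data. Shared peaks, the excess of zinc finger last exons over promoters, and GC and repeat content exceeded chance under each alternative run for them. In the 500 bp around the summit the GC excess was smaller (46.4% against 41.9%) and the repeat excess larger (41.1% against 34.1%). Shared shares of replicate 1 peaks ranged from 20.3% (80% of the length) to 43.9% (1 bp), against 35.1%. Of 732 values under alternatives, 642 were counted as unchanged, under criteria that differed by type of value. The count includes lists called neither with replicated peaks nor under the alternative, so it does not show that their direction was kept. It also includes small shifts in the number of called lists, such as 6 above chance in bodies with pooled peaks against 4. Where a value moved, the cause was not tested, except where the alternative's construction gives it. The correlation of folds was 0.186 with a −log10 q of at least 2, 0.268 at 5 and 0.292 for −log10 p. Replicated peaks with peaks of both replicates made up 67.9% with 1 bp of overlap, 25.8% with −log10 q of at least 2 and 3.39% at 5, which removes peaks from the replicates' lists. Lists above chance in bodies numbered 4, but 5 at −log10 q of 5 and with either replicate left out, 6 with pooled peaks and in the full list of replicate 2, 2 with random placement, which spreads peaks over more genes, and 7 with bodies extended by 5 kb. Lists below chance in bodies numbered 1, but 3 and 4 in the full lists of replicates 1 and 2, 6 with random placement, 2 among protein-coding members, 0 with 10% of the body covered, and 1 to 2 without either replicate. Lists above chance in promoters numbered 4, but 3 at −log10 q of 5 and with pooled peaks, 5 in the full list of replicate 2 and with the other promoter windows, and 2 without replicate 2. Lists below chance in promoters numbered 1, but 0 without either replicate, at −log10 q of 5 and with pooled peaks, and 2 in each full list of a replicate and within 5 kb of transcript starts. The deficit of UTRs and non-coding exons was not called at −log10 q of 5 (2.33%), nor was that of promoters (6.11%), and counting bases turned promoters to a small excess (6.61%). Coding exons were called above chance at −log10 q of 5 (1.21%), in the full lists (1.21% and 1.17%), by bases (1.54%) and without either replicate (1.19% to 1.21%). The density ratio of chromosome 7 was 2.30 at −log10 q of 5 and 2.15 by covered bases. Domains of at least 20 kb numbered 22 with merging within 2 kb, 1029 within 10 kb (329 after random placement) and 145 at −log10 q of 5. No paired analysis was possible because there is 1 group. Read depth is unknown, so what it limits cannot be stated.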

Other observations

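The family scan, the recurring sequence of peaks and the test without chromosome 7 below were chosen only after the results were seen. A scan of 255 families of at least 10 protein-coding genes sharing a name stem took in groups that no list held. Bodies of 5 families were covered more than after random shifts and 10 less (5000 shifts, adjusted permutation p below the threshold). Above chance were the beta protocadherin genes (50.8% of bases against 1.16%), the 34 secretoglobin genes (28.4% against 2.24%), the Zfp genes (3.56% against 1.41%), the 10 Mroh genes (6.89% against 1.03%) and the 17 Nlrp genes (13.1% against 2.17%). Nlrp genes include oocyte proteins, and 14 of the 17 had a marked body, against 22 of 22 beta protocadherin, 204 of 394 Zfp, 9 of 34 secretoglobin and 5 of 10 Mroh genes. The secretoglobin and Mroh values thus rest on a minority or an even split of members, and peaks covered 88.6% of the 35304 bp of Mroh2a. Adjusted p-values were 0.0204 for the first 3 and 0.0255 for Mroh and Nlrp. Chromosome 7 held 13 of the 17 Nlrp and 30 of the 34 secretoglobin genes, and chromosome 18 all 22 beta protocadherin genes. Neighbouring genes can lie in the same domain, so the counts of marked members are not counts of independent genes.

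Families below chance included Med genes, subunits of the Mediator complex (0.135% against 1.13%), Kdm genes, histone demethylases (0.125% against 1.2%), Eif genes, translation initiation factors (0.329% against 1.18%), and Mrps genes, mitochondrial ribosomal proteins (0.0856% against 1.16%). The others were Fam, Wdr, Usp, Cdc, Arid and Sema. Introns held fewer peaks than after shifts genome-wide, so such deficits need not be particular to these families. Recurring sequence differed between peaks and shifted positions in both directions, depending on the measure. The shifted values here come from a single random shift per chromosome, so they have no range and no p. Of replicated peaks, 2.06% consisted mostly of 31-mers found elsewhere in the genome, against 15.9% of shifted ones. Only 31-mers found once were held by 28.05%, against 50.81%. Of all their 31-mers, 11.54% recurred, against 18.32%. Shifted positions thus lay in mostly recurring sequence more often than peaks, which the tests against shifts do not account for. Among the strongest peaks, recurring 31-mers made up 58.9% of the Y peak near Gm29277 and 44.2% of that in C230088H06Rik. They made up 0% of the Klf14 peak and of the Zfp68 peak with a fold of 10.3, but 5.48% of another Zfp68 peak, with a fold of 9.68.

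The last coding exons of Zfp-named genes were covered far more than their promoters. Exons with at least 95% of their 31-mers found once in the genome, 208 of 349, were covered to 32.2%, above the highest of 1000 shifts (5.57%), which argues against reads shared between paralogs. Last coding exons of other genes, weighted to the same GC content, were covered to 1.87%, which argues against GC content alone. Without chromosome 7 the difference was 19.48 percentage points against a highest shift of 2.92, which argues against a single cluster. No biological explanation was tested.

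Of the peaks of replicates 1 and 2, 35.1% and 31.9% were shared with the other. Recurring 31-mers made up 9.44% of unshared and 11.6% of shared replicate 1 peaks, a difference of -2.11 points, which argues against recurring sequence. Of the top 5000 replicate 1 peaks by p, 80.5% were covered by some replicate 2 peak, against the share above for all, so weak peaks near the calling threshold may account for part of the unshared ones. Cutting both lists did not raise the share of replicate 1 peaks, which was 30.8% among the top 20000 of each, 28.8% among the top 5000 and 27.9% with a −log10 q of at least 5. The share of replicate 2 peaks was 31.8% and 30.4% with the first 2 cuts. It rose with the q cuts, to 35.5% with a −log10 q of at least 2 and 34.4% at 5, while that of replicate 1 was 29.8% at 2. Such cuts set a new threshold in both lists, so how much weak peaks account for stays open. No biological difference between the replicates is given by the labels, and depth stays open.

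Replicated peaks had a higher GC content than chance placement. Intergenic peaks alone had 48.6% GC against 40.9%, with a highest of 41.1% in 100 shifts, which argues against gene sequence as the whole cause. Promoters in the highest of 5 GC bins were marked in 1.77%, against 5.92% after shifts with a lower bound of 5.12%. The prediction for a general preference of the libraries for GC-rich DNA, at least as much marking as after shifts, was thus not met. A high GC content alone did not bring peaks to these promoters. They may carry less of the mark than other DNA, so the test cannot tell whether the libraries favour GC-rich DNA. A preference that acts only on DNA carrying the mark was not tested, and neither was any biological cause.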
